A study of Mus musculus with 2 samples.

How the data were processed

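The labels describe total RNA of testes from Stambp-ps1+/- and Stambp-ps1-/- mice at 23 dpp, extracted with Trizol. From 20 µg of it, RNA of 15 to 40 nt was cut from a 15% denaturing gel and made into directional libraries with the TruSeq Small RNA kit. Each deposited table lists every distinct read sequence with its raw count of reads, with no scaling, as the values show: whole numbers from 1, each sequence once. The tools and settings for adapter trimming, length filter and any alignment are not given in the sources used here. The tables held sequences of 18 to 32 nt, and 0.188% of KO-named and 0.190% of het-named reads contained an undetermined base. The 2 tables shared 2368506 of 12016007 distinct sequences, which held 90.7% of KO-named and 90.6% of het-named reads. Since the record lists both tables under the Stambp-ps1-/- sample, each was named by the word in its deposited name and put in no genotype group.

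Reads were matched with 0 mismatches to the transcripts of GENCODE M21 with bwa 0.7.19, on both strands, and the matches were projected to GRCm38 coordinates. A genome sequence was not used here, so a place is a distinct position of the read's start among annotated transcripts, and reads from unannotated regions stayed unmatched. A read with several places counted by the share 1 over the number of places, and the few sequences with over 2000 matches were left out. Where the Stambp-ps1 loci, Stambp, Gm10069 and Fkbp4 are described singly, each read counted in full unless stated otherwise. Values are reads per 1000000 reads of the table (RPM), and reads of 24 to 32 nt stand for piRNAs. Log2 ratios are KO-named over het-named with 0.5 reads added to each count, and plain ratios and folds have nothing added. Genes needed at least 200 reads in the tables together. piRNA clusters were windows of 10 kb with at least 100 RPM of 24 to 32 nt reads in the summed tables, joined when within 20 kb. The miRNAs were counted from reads of 19 to 25 nt over annotated hairpins. For the ping-pong mark, overlaps of 1 to 20 nt between read starts on opposite strands were counted and the overlap of 10 nt was given as a z score against the others. Stambp mRNA was also searched with up to 2 mismatches, and Gm18009 was aligned to it with Biopython 1.88. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

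With 1 library per table no test between groups was run. Shares and RPM values carry exact Clopper-Pearson intervals at 95%, ratios carry the interval of the conditional binomial, differences of shares a normal approximation, and medians carry bootstrap intervals from 2000 resamples of genes, clusters or miRNAs, which do not measure variation between animals. Each miRNA list with at least 3 measured members was ranked among 10000 random lists matched for abundance. The gene counts were tested on simulated data: of 2000 simulated reads 100% were placed, and for 200 of 4552 genes changed by a known amount, the intervals held the true ratio for 98% of genes at a log2 of -2 and 94% at a log2 of -1. At a true log2 of -1, 56% of the genes came out at or past 1 in size, and at 0 none did. The simulated reads were cut from the same transcripts they were matched to, and the counts carried counting error alone. High placement and coverage were therefore built in, and the simulation checks the calculation only. PCR duplicates and variation between animals were not simulated.

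The comparisons, the lists and the rule for the genes named were fixed before the data were examined. The rule took Stambp-ps1 and Stambp always, and the 10 clusters and 10 miRNAs with most reads. Of clusters, miRNAs and genes with at least 200 reads, it took up to 10 highest and 10 lowest log2 ratios among those at or past 1 in size. It also took up to 4 members per list. Mir146 and Mir142 stand for the listed Mir146a and Mir142a, and Mir469 is not in the annotation. Some steps departed from the plan. The total was planned over 15 to 40 nt, but the tables hold 18 to 32 nt, so all reads were the total. Reads with 1 place in the genome became reads with 1 place among annotated transcripts. The ratio for Stambp antisense reads became a difference in RPM because both counts were 0. The alternatives tried were other scalings (24 to 32 nt, miRNA or cluster reads), other lengths, distinct sequences in place of reads, reads with 1 place alone, other count minimums and up to 2 mismatches. Of the alternatives, 4 were chosen after seeing the data: cluster reads without annotated small RNA genes, scaling to the median gene, each pair of positions counted once for the ping-pong mark, and miRNAs with at least 50% of reads at their main start.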

Results

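Small RNA of 23 dpp mouse testes was sequenced to study piRNAs, the small RNAs of the germ line that guide PIWI proteins. The labels describe 2 samples, 1 of Stambp-ps1+/- and 1 of Stambp-ps1-/- mice, both on the C57BL/6 background. Stambp-ps1 is a pseudogene of Stambp, which encodes a deubiquitinase of the endosome. There were 2 tables of distinct read sequences with their counts. The deposited record puts both tables under the Stambp-ps1-/- sample and none under the Stambp-ps1+/- sample, although the name of 1 table carries the word KO and the name of the other the word het. They are therefore called the KO-named and the het-named table, and neither was assigned to a genotype. The KO-named table held 54384974 reads of 6895028 distinct sequences, and there were 62773871 reads of 7489485 distinct sequences in the het-named table, all of 18 to 32 nt. With 1 library per table there were no replicates and no test between groups was possible. Intervals of single shares, RPM values and ratios are exact 95% binomial intervals, those of share differences use the normal approximation and those of medians a bootstrap. The exact intervals and the floors set by 3 reads (0.0552 reads per 1000000 reads, RPM, in the KO-named and 0.0478 in the het-named table) cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

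The first question was whether small RNAs of Stambp-ps1 differed between the tables. The symbol is used for 2 loci, and the labels do not say which was mutated or how. The RefSeq pseudogene Stambp-ps1 is Gm18009 (ENSMUSG00000107505.1) in GENCODE, a processed pseudogene at chromosome 6, 128447084 to 128448398 on the minus strand of GRCm38. Reads of 24 to 32 nt from Gm18009 were nearly confined to the het-named table, with 2700 reads there and 25 in the KO-named table. This was 43.0 RPM (41.4 to 44.7) against 0.460 (0.297 to 0.679), or 93.6-fold more in the het-named table (63.2 to 145). The log2 ratio of the KO-named over the het-named table was -6.52, the lowest of 4552 annotated genes with at least 200 such reads, and the second lowest was -1.49. With distinct sequences counted in place of reads the log2 ratio was -4.50.

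The Gm18009 reads had the features of piRNAs and lay almost wholly antisense to the pseudogene. All 2700 reads of the het-named table and 24 of the 25 in the KO-named table were antisense, and all had 1 place among the annotated transcripts. The antisense reads came from 553 distinct sequences in the het-named table and 21 in the KO-named table. Their first base was U in 89.4% (88.1 to 90.5) of the het-named and 87.5% (67.6 to 97.3) of the KO-named reads, with a median length of 30 and 29 nt. The reads covered both exons of Gm18009, and all 22 bins of 50 nt that held reads were higher in the het-named table. Antisense reads of 18 to 23 nt numbered 36 in the het-named and 3 in the KO-named table. GENCODE gives the symbol Stambp-ps1 to another pseudogene, at chromosome 8, 60792221 to 60793428, which RefSeq calls Stambp-ps2 with Stambp-ps1 as a synonym. That copy had 1 read of 24 to 32 nt in the KO-named table and 0 in the het-named table, so a difference there was not detectable at this depth. The 1 read had several places, so it cannot be assigned to that copy.

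**Figure D1:**
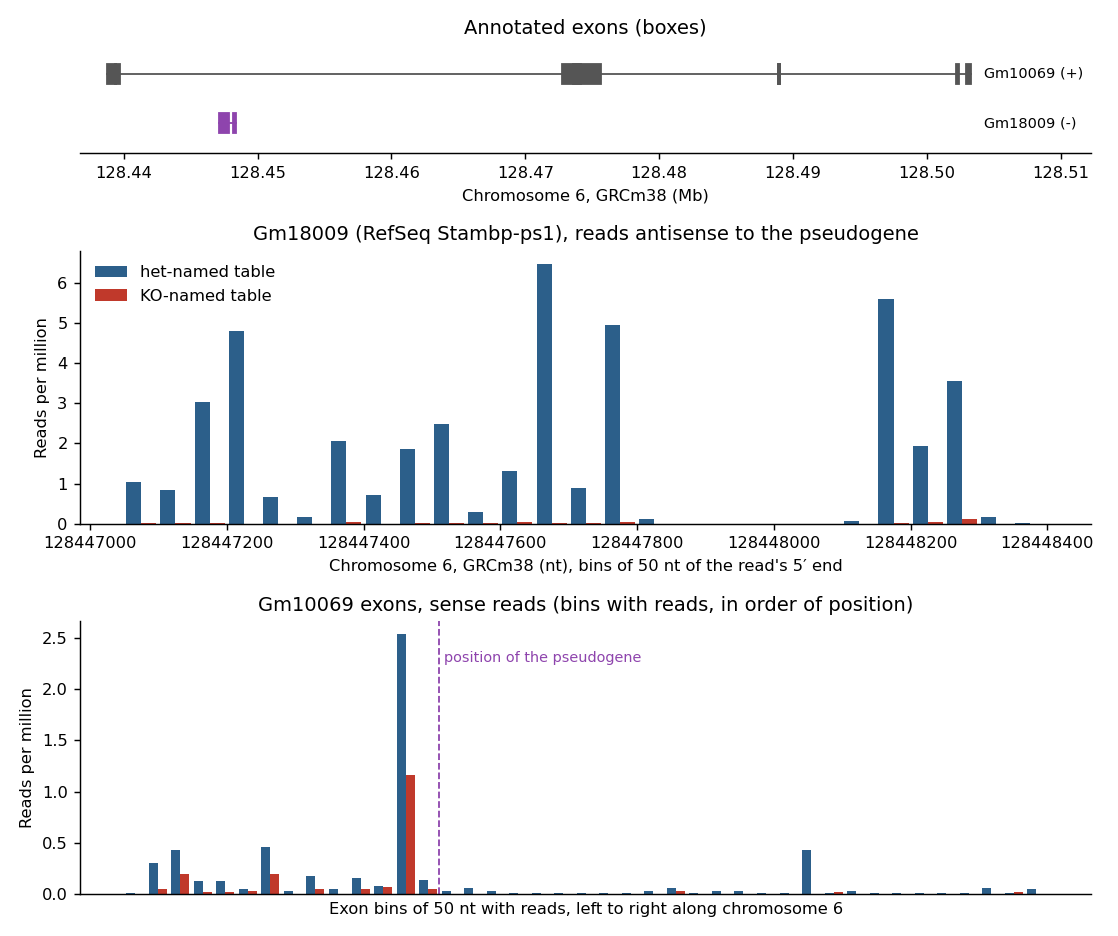
Annotated exons on chromosome 6 (top), antisense reads of 24 to 32 nt over Gm18009 in bins of 50 nt (middle) and sense reads at 1 place over the exons of Gm10069 (bottom), in RPM of each table. The het-named bars stand above the KO-named bars in all 22 bins of Gm18009 that hold reads, and beyond the pseudogene Gm10069 has 70 het-named and 4 KO-named reads.

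The next question was whether either table held small RNAs complementary to the parent Stambp mRNA (ENSMUSG00000006906.10, chromosome 6, 83543211 to 83572729, minus strand). With an exact match there were 0 antisense reads of 24 to 32 nt in either table. The floor of 3 reads is 0.0552 RPM in the KO-named and 0.0478 in the het-named table, and the exact 95% upper limits for 0 reads are 0.0678 and 0.0588 RPM. Over all lengths there was 1 such read, in the KO-named table. Gm18009 aligned with Stambp over 647 bases at 74.2% identity, between positions 804 and 1520 of the mRNA. With up to 2 mismatches allowed, 120 reads of the het-named table and 3 of the KO-named table were complementary to Stambp mRNA. Of these, 113 and 2 matched Gm18009 exactly, which was 4.19% of the antisense Gm18009 reads of the het-named table. The median Gm18009 read of that table had 12 mismatches to the mRNA. Sense reads of Stambp, measured the same way with exact matches, numbered 493 in the het-named and 327 in the KO-named table, a ratio of KO-named over het-named of 0.766 (0.664 to 0.882). The log2 ratio was -0.38. Coding genes with at least 90% sense reads had a median of 0.23 and a lower 5% tail at -0.09. Why Stambp lay below that tail was not tested.

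The genes around Gm18009 were compared next. Gm18009 lies within an intron of the long noncoding RNA gene Gm10069 (ENSMUSG00000059659.7, chromosome 6, 128438757 to 128503281, plus strand), and its antisense reads run on the strand of Gm10069. Sense reads of Gm10069 at 1 place were also lower in the KO-named table, 109 against 364 reads, a ratio of 0.346 (0.276 to 0.429). With reads of several places included, each counted in full, they were 360 and 649, a ratio of 0.640 (0.561 to 0.729). Shared over their places, the sense reads came to 153.8 and 412.5. On both strands, that way of counting gave a ratio of 0.466 (0.389 to 0.557). In the exons before the pseudogene the sense reads at 1 place were 105 and 294 (ratio 0.412, 0.327 to 0.517). In the exons after it they were 4 and 70 (ratio 0.0660, 0.0175 to 0.177). Fkbp4, an immunophilin gene that starts beside Gm10069 on the minus strand, had 31 and 33 sense reads at 1 place, a ratio of 1.08 (0.642 to 1.83). Its shorter sense reads at 1 place, of 18 to 23 nt, were lower in the KO-named table, 12 against 34 (ratio 0.407, 0.192 to 0.806). Short reads also made up less of the whole KO-named table. Those of 18 to 20 nt were 4.08% against 7.83%, and those of 21 to 23 nt 16.5% against 17.3%. The lower short reads cannot be taken as local to Fkbp4. Antisense reads of 24 to 32 nt over Fkbp4, nearly all with several places and each counted in full, numbered 2880 and 4299 (ratio 0.773, 0.737 to 0.811). The split of Gm10069 into exons before and after the pseudogene, and the choice of these neighbours, were made after the values of Gm18009 were seen.

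Across the annotated genes, reads of 24 to 32 nt differed little for most genes, and Gm18009 stood far below the others. The median log2 ratio over 4552 genes was 0.20 (0.20 to 0.21), with the bulk of genes, from the lower to the upper 5% tail, between -0.13 and 0.50. At or past 1 in size, 1 gene was higher in the KO-named table and 15 were lower. The higher gene was the small nucleolar RNA Gm24837, with 135 and 73 reads (log2 1.09). The 10 lowest were Gm18009, Gm23388 (-1.49), Mir6236 (-1.16), Gm42418 (-1.13), AY036118 (-1.13), Gm10069 (-1.10), CT010467.1 (-1.09), Gm24187 (-1.08), Gm23935 (-1.06) and Gm24245 (-1.06). CT010467.1 is annotated as ribosomal RNA at chromosome 17, 39846353 to 39848827, and Gm42418 and AY036118 lie within the same interval. Reads of CT010467.1 and AY036118, both on the minus strand, were 99.99% antisense. Those of Gm42418, on the plus strand, were nearly all sense (0.00975% antisense). The reads thus ran on the plus strand, and a read in the shared part counted for each entry. Gm23388, Gm24187, Gm23935 and Gm24245 are short entries annotated as miRNAs. Gm23935 and Gm24245 had the same counts, 2293.3 KO-named and 5502.7 het-named reads each. The 15 lower entries are therefore not 15 separate sources of reads. Protein-coding genes had a median of 0.21 over 3384 genes, with 0.22 for the 98 whose reads were at least 90% antisense and 0.23 for the 2427 whose reads were at least 90% sense. Processed pseudogenes had a median of 0.17, and Gm18009 was the only one of them at or below -1.

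**Figure D2:**
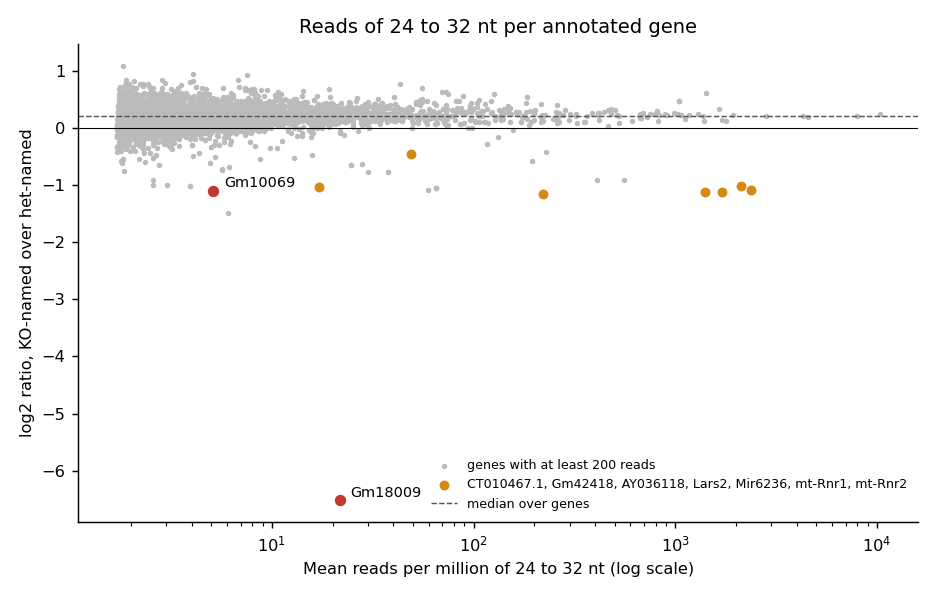
Each point is an annotated gene with at least 200 reads of 24 to 32 nt in the tables together; the horizontal axis is its mean RPM (log scale) and the vertical axis the log2 ratio of the KO-named over the het-named table. Gm18009 lies at -6.52 and all other genes between -1.49 and 1.09, with the median at 0.20 (dashed line).

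The question for the piRNA clusters was whether piRNA output in general differed between the tables. Most clusters had a slightly higher RPM in the KO-named table, and by nearly the same amount. The median log2 ratio over 114 clusters was 0.23 (0.21 to 0.25), with 107 clusters above 0, 7 below 0, and 103 within 0.25 of the median. Of these clusters, 20 consisted mostly of annotated small RNA genes such as miRNA hairpins. With reads of such genes left out, an alternative chosen after seeing the data, 95 clusters remained, again with a median of 0.23. Of them 1, led by Lars2, was at or below -1. The cluster with most reads, led by the noncoding RNA Gm49794 at chromosome 17, 27300001 to 27370000, had 16559 RPM in the KO-named and 14049 in the het-named table (log2 0.24). The clusters led by Gm21269 on chromosome 7 (0.20), 1700001L05Rik on chromosome 15 (0.20), Nemp1 on chromosome 10 (0.23), AC140207.2 on chromosome 18 (0.13), 1700029M20Rik on chromosome 4 (0.13), and Gm5878 (0.33) and Gm18609 (0.26) on chromosome 6 behaved alike. In these 8 clusters 84.8 to 96.6% of reads began with U. The other 2 of the 10 with most reads, led by CT010467.1 (-1.05) and Lars2 (-1.01), were lower in the KO-named table, and 24.4% and 25.1% of their reads began with U. Whether the reads of the Lars2 window are piRNAs or come from another RNA was not examined. Together with the window of Mir6236 (-1.16, 14.4% of reads with a first U), they were the 3 clusters at or below -1, and no cluster reached 1. The other clusters below 0 were led by AA474408 (-0.91), Gm15564 (-0.90), Smyd5 (-0.28) and Wdfy3 (-0.18). Of their reads 16.1%, 30.2%, 99.6% and 88.2% began with U. Most of the clusters below 0 thus lacked the first U of piRNAs. Scaling to miRNA reads instead of all reads shifted every log2 ratio down by the same amount, 0.26, which brought the cluster median to -0.03, so its direction depended on the scale. The clusters cover annotated exons alone and held 11.3% of the 24 to 32 nt reads of the KO-named and 10.8% of those of the het-named table, or 9.99% and 9.44% without the small RNA genes.

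The size and first base of the reads were compared to see whether the piRNA population as a whole was present in both tables. Both tables had a main peak at 30 nt, the length usual for pachytene piRNAs bound by MIWI, and smaller peaks at 27 nt, with 9.56% of KO-named and 8.88% of het-named reads, and at 22 nt, the length of miRNAs, with 8.22% and 7.79%. Reads of 24 to 32 nt made up 79.4% of the KO-named and 74.9% of the het-named table, a difference of 4.49 percentage points (4.47 to 4.50). Reads of 18 to 20 nt made up 4.08% and 7.83%. Among reads of 24 to 32 nt, 78.8% in the KO-named and 73.6% in the het-named table began with U, a difference of 5.16 points (5.14 to 5.17). The share with A at the tenth base was 29.6% and 29.9%. Pairs of reads on opposite strands overlapped most often by 10 nt, the mark of ping-pong amplification, in 31.4% of pairs in the KO-named and 31.2% in the het-named table. The z score of the 10-nt overlap was 20.1 and 19.1, but it was 1.44 and 1.24 when each pair of positions was counted once, and 20 nt was then the most frequent overlap.

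**Figure D3:**
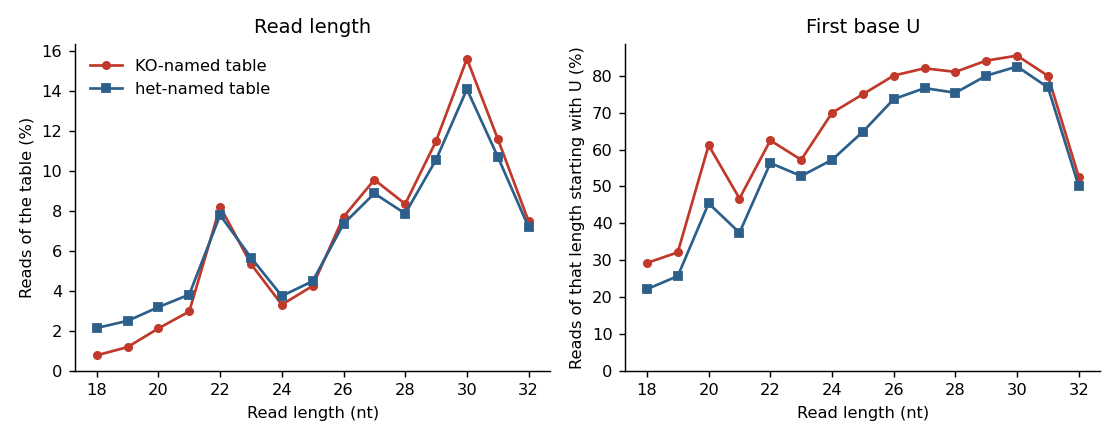
Left, percent of the reads of each table at each length in nt; right, percent of the reads of that length that begin with U. At 30 nt the KO-named table has 15.6% of its reads, against 14.1% in the het-named table, and 85.5% and 82.5% of these begin with U.

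The classes of annotated RNA were compared among the reads that matched a transcript, 26.3% of the KO-named and 23.8% of the het-named reads. Ribosomal RNA genes stood out: they took 1.12% of matched reads in the KO-named and 2.82% in the het-named table. With reads on either strand counted, their log2 ratio was -1.52 at 18 to 20 nt and -1.20 at 21 to 23 nt. It was -0.99 at 24 to 28 nt and -1.13 at 29 to 31 nt. The miRNAs took 47.3% and 44.2% of matched reads, piRNA clusters 30.2% and 29.7%, and sense reads of protein-coding exons 11.9% and 12.8%. Antisense reads of protein-coding exons took 1.88% and 2.02%, and pseudogenes 1.49% and 1.57%. Most nuclear tRNA genes and the full ribosomal RNA precursor are not among the annotated transcripts, so these shares leave their reads out. They also leave out most reads of piRNA size. Only 17.0% of KO-named and 16.1% of het-named reads of 24 to 32 nt matched a transcript. Of the unmatched reads of that length, 78.0% and 72.5% began with U. The shares are therefore not the make-up of the libraries.

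The miRNAs were compared because they mark the cell types of the testis. They were slightly higher as a group in the KO-named table, and of the cell type lists the blood miRNAs stood highest. The median log2 ratio over 255 miRNAs with at least 200 reads was 0.30 (0.26 to 0.33), with 208 above 0 and 47 below. At or past 1 in size were Mir196b (1.17, from 141 and 72 reads), Mir879 (-1.28, from 68 and 192 reads), Mir6236 (-1.21) and Mir6240 (-1.02). Mir6236 and Mir6240 had only 13.6% and 23.3% of their reads at their most frequent start, against 97.7% for Mir879. The 10 miRNAs with most reads were Mir10b (0.33), Mir871 (-0.07), Mir143 (0.22), Mir22 (0.64), Mir470 (0.01), Mir34c (0.47), Mir191 (0.20), Mir30a (0.37), Mir148a (0.49) and Mir99b (-0.39). Scaling to miRNA reads lowered every log2 ratio by 0.26 and brought the median to 0.04, with 143 miRNAs above 0 and 112 below. Mir196b was then at 0.91 so that none reached 1, and 3 stayed at or below -1. On that scale the medians of the spermatogonia and proliferation list (0.24 here) and of the Sertoli and other somatic testis list (0.19 here) lie below 0.

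Of the lists tied to germ cells, the X-linked testis miRNAs ranked highest. Each list's median was ranked among 10000 random lists of miRNAs of like abundance, a rank that was not adjusted for the 8 lists ranked. Of the meiotic and later germ cell list, 6 of 8 members were measured, with a median of 0.27 (percentile 38.2), including Mir34b (0.42), Mir449a (0.33) and Mir184 (-0.37). The X-linked testis miRNAs, 20 of 21 measured, had a median of 0.38 (percentile 94.8), from Mir871 at -0.07 to Mir463 at 0.83, with Mir878 (0.67) and Mir881 (0.57) near the top. The spermatogonia and proliferation list, 11 of 19 measured, had a median of 0.24 (percentile 33), with Mir21a at 0.57 and Mir19b-1 at 0.06. The let-7 family, all 12 measured, had a median of 0.37 (percentile 84.5), from Mirlet7b at -0.06 to Mir98 at 0.59. Family members share sequences, so they are not independent of each other.

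Among the lists of other cell types, the blood miRNAs lay highest above the rest. Mir451a of red blood cells (0.91), Mir223 of myeloid cells (0.91) and Mir142 of blood cells in general (0.52) were the 3 measured of 4. Their median was 0.91, but their sum was low, 63.7 RPM in the KO-named and 43.1 in the het-named table. Of these sums Mir142 made up 55.1 and 38.5 RPM. Mir451a had only 191 and 117 reads, and Mir223 276 and 169. The median of 0.91 lay at percentile 99.6. The epithelial list, 5 of 6 measured, had a median of 0.44 (percentile 95.8), with Mir429 at 0.76 and Mir204 at 0.10. The muscle list, 3 of 4 measured, had a median of 0.39 (percentile 77.5), with Mir133a-1 at 0.73 and Mir145a at 0.39. The Sertoli and other somatic testis list, all 5 measured, had a median of 0.19 (percentile 11.2), with Mir10b at 0.33 and Mir202 at -0.04. Endothelial Mir126a lay at 0.26 and neural Mir9-2 at 0.46, and liver Mir122 did not reach 200 reads. No measured member of any list was at or past 1 in size.

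**Figure D4:**
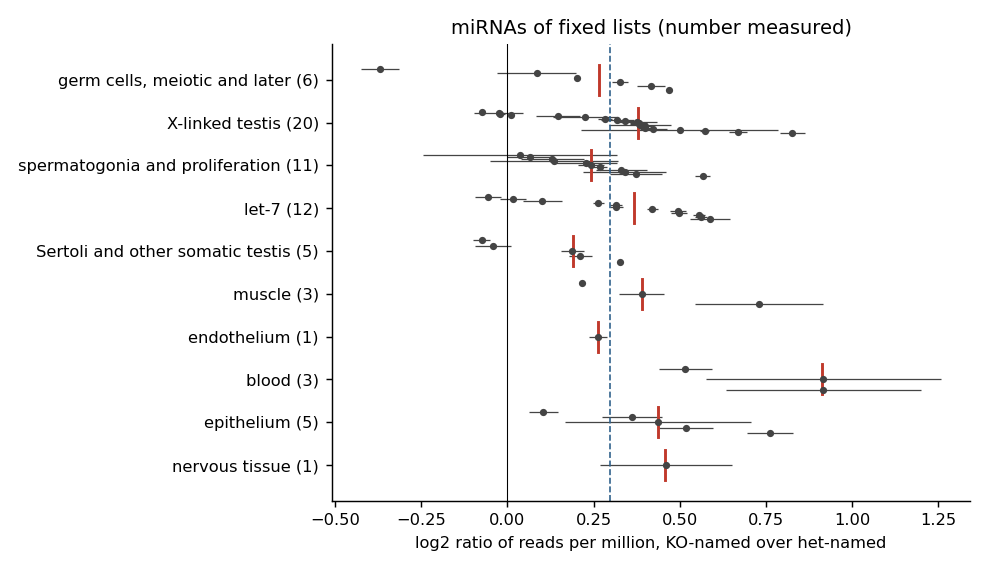
Log2 ratio of RPM, KO-named over het-named table, for each measured miRNA of the fixed lists (points, with 95% intervals for counting error); red marks are list medians and the dashed line is the median of all miRNAs, 0.30. The medians run from 0.19 for the Sertoli and other somatic testis list to 0.91 for the blood list.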

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

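Scaling to the median gene, clusters without small RNA genes, miRNAs with a main start, and counting each pair of positions once were chosen only after the result was seen. Of 44 alternatives, 18 stayed the same, 25 moved and 1 reversed, judged by the interval of the reported value or, for the overlap z scores, which have none, by a shift of 1. The cause was not tested unless given. Scaling to miRNA reads turned the cluster median to -0.0295, and scaling to the median cluster set it to 0 by construction. The median of miRNAs became 0.20 with a minimum of 20 reads, 0.0397 scaled to miRNA reads and 0.0524 scaled without the most abundant miRNA. The log2 ratio at Stambp-ps1 was -4.50 over distinct sequences, and all its other alternatives stayed within its interval. The difference in Stambp antisense reads was -1.86 RPM with up to 2 mismatches. The piRNA-size difference was 4.87 points at 26 to 31 nt, 3.35 at 29 to 31 nt and 3.96 over distinct sequences, and the first-U difference 4.37 at 26 to 31 nt and 3.36 over distinct sequences. With 1-place reads the class differences were 2.79 points for miRNAs, -2.05 for rRNA, 0.0882 for mitochondrial tRNA and other small RNA, 0.554 for clusters, -0.770 and -0.0123 for coding sense and antisense, -0.0431 for pseudogenes and -0.556 for lncRNA or other. The overlap z score was 18.3 (KO-named) and 17.3 (het-named) at 26 to 31 nt, 22.2 and 21.2 without clusters, and 1.44 and 1.24 with each pair of positions counted once. Depth limits the search for Stambp antisense reads to levels above 3 reads, 0.0552 and 0.0478 RPM. The exact match limits it too, since 0 of the antisense Gm18009 reads of either table matched Stambp mRNA without a mismatch.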

Other observations

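The tests of depth or overall piRNA content, of size selection and both tests on Gm10069 were chosen only after the result was seen; those of carried-over reads and of RNA breakdown were set before it.

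The most abundant sequence of 24 to 32 nt was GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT, a fragment from the 5′ end of a glycine tRNA, which matched no annotated transcript. It had 15051 RPM in the KO-named and 12095 in the het-named table (log2 0.32). Of 4 similar sequences among the 20 with most reads, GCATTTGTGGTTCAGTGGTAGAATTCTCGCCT (0.33) and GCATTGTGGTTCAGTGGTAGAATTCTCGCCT (0.23) were also higher in the KO-named table. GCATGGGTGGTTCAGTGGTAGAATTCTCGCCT (-0.34) and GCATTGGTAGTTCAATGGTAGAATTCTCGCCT (-0.50) were lower there. Mitochondrial RNAs also split: the 14 mitochondrial tRNA genes had a median log2 ratio of 0.34 (0.04 to 0.72) for reads of 24 to 32 nt, and the 6 mitochondrial mRNA and rRNA genes a median of -0.57 (-0.82 to -0.48).

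Antisense reads of Gm18009 were far lower in the KO-named table. A difference in depth or scaling shared by all loci is argued against by the log2 ratio scaled to cluster reads, -6.69 on both strands. For overall piRNA content the cluster median was 0.23. RPM scaling and piRNA-size shares of 79.4% and 74.9% left little room for a median as low as at Gm18009, so it cannot test this. It shows only that Gm18009 differed from the annotated clusters, which held 11.3% and 10.8% of the 24 to 32 nt reads. Carry-over from the het-named library at a rate common to all sequences is argued against as the source of all 24 remaining antisense reads by the bound set beforehand: of 6606 other sequences with at least 1000 het-named reads, 1 was kept at 0.130% (0.0157 to 0.470), below the 0.889% (0.569 to 1.33) at the locus. That rests on 1 sequence, which matched no annotated transcript, and the lowest of the 1072 matched sequences was kept at 7.62%. A genotype difference at the locus stays open and was not tested, since the record puts both tables under Stambp-ps1-/-.

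Reads of ribosomal RNA genes such as CT010467.1, counted on either strand, were lower in the KO-named table. Of the CT010467.1 reads of 24 to 32 nt, 99.99% ran antisense to the annotated gene. Which transcript they came from was not examined. Size selection that let more short inserts into the het-named library is argued against as the whole cause, because the log2 ratio was still -1.13 (-1.15 to -1.11) at 29 to 31 nt. Stronger breakdown of long RNA in the het-named library stays open. Sense reads of 18 to 23 nt that do not begin with U had a median log2 ratio of -0.42 (-0.61 to -0.23) over 29 nuclear coding genes. Of these genes 28 were below 0, and the median lay between the bounds set beforehand. Sense reads of that length that begin with U had 0.05 (-0.02 to 0.15) over 69 genes, 29 of them below 0. At 24 to 32 nt, sense reads that do not begin with U had a median of 0.21 (0.20 to 0.23) over 453 coding genes. Those that begin with U had 0.26 (0.25 to 0.27) over 2159. That length includes piRNAs, so these similar medians cannot speak for or against breakdown. The 6 mitochondrial mRNA and rRNA genes had a median of -0.57 (-0.82 to -0.48) at that length. Mitochondrial rRNA is part of the pattern itself, and the 14 mitochondrial tRNA genes had a median of 0.34 (0.04 to 0.72). No bound was set for mitochondrial genes, so their values cannot decide whether breakdown was the cause. A difference of genotype was not tested.

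Reads of Gm10069 were lower in the KO-named table on both sides of Gm18009. A common reduction along the whole of Gm10069 is argued against by the after-to-before ratio of ratios, 0.160 (0.0415 to 0.445). That a few heavily amplified sequences of the het-named library made this difference is argued against by the same value over distinct sequences, 0.195 (0.0485 to 0.575). Both rest on only 4 KO-named reads beyond the pseudogene. No biological explanation was tested.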
